A study of Mus musculus with 6 samples.

How the data were processed

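Spleen RNA of female NOD mice, in 3 vehicle and 3 MOTS-c samples, was read on 1-colour Agilent arrays. Per the file headers, each array was scanned for Cy3 and its intensities were extracted with Agilent Feature Extraction 11.0.1.1, which subtracted the background within each array and gave a processed signal intensity per spot; the signals were not normalized between arrays. The deposited table of the authors holds log2 values of the same processed signals, which the values show to be quantile normalized between the 6 arrays, for 31692 probes that were all well above background on all 6 arrays. The processed signals in that table equalled those of the scanner output for 100% of its probes on each array, within a relative tolerance of 0.0001. The same deposited table gives the authors' signed fold of MOTS-c over vehicle as a score per probe, and a p-value with its Benjamini-Hochberg adjustment from a test of the authors. In the authors' deposited table, 4261 probes had a p-value under 0.05 and 0 an adjusted one, the smallest being 0.370. At a fold of 2 or more and a p-value under 0.05, the authors' deposited table has 67 probes higher and 690 lower with MOTS-c.

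Group and replicate number of each sample were taken from the titles. For vehicle 3 and MOTS-c 3 the description gives another number than the title, so the block on replicate number and the pairing by number rest on the titles. The labels do not say that the samples of a group came from separate mice, so p-values measure only the spread between these samples. Each array had 62976 spots, of which 59305 were not controls, and 97 to 145 spots per array that Feature Extraction had marked as outliers were left out. Spots of 1 probe were averaged on the log2 scale. The value of a probe was log2 of its processed signal minus the array's 75th percentile of it, so a level of 0 is the signal of that percentile. Symbols were found for 38977 of 56605 probes, for 26241 of them through the gene ID of the array table and for 11826 through an accession in the reference table of gene names, and 17628 probes stayed unnamed. Probe coordinates are those of the array design on mm9, per the file headers; no genome sequence of that build was used, so the place of a probe within exons or untranslated regions was not determined.

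Probes well above background on all 3 arrays of at least 1 group were tested, 33734 in all. A gene was represented by its brightest tested probe, which left 22484 genes, and an unnamed probe stood for itself. Where probes of a named gene went in opposite directions, both values are given. MOTS-c was compared with vehicle by limma 3.58.1 in R 4.3.3 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; differences are MOTS-c minus vehicle. Where a gene was not well above background on any array of a group, its difference is given as a bound. The bound sets the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the lowest signal well above background and the probe's own. With 3 arrays against 3, an exact permutation test cannot go below a p of 0.1, so no single value was tested that way.

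A set of 36 gene lists covering spleen cell types, T cell states, other tissues that a spleen sample can hold, and metabolic and signalling processes was tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists with at least 5 tested members. Of 667 listed genes, 615 were tested, and 18 genes belong to more than 1 list. Beside it stand camera with an estimated correlation, camera on ranks, and fry, which asks whether the genes of a list move on balance one way. The lists, the tests, the thresholds, the alternatives and the rule for named genes were set before the data were examined. By that rule the genes named are the 12 with the largest difference in each direction past the threshold, filled where fewer passed with the largest differences at an unadjusted p under 0.01 whose groups do not overlap, the 4 members with the smallest p of each list that passed, up to 2 members of other lists that are described, and a fixed panel of T cell and signalling genes. Genes known only by a clone or model name were counted and not named, and some genes that the rule names are not reported here. Chosen only after the data were seen were the lists outside the threshold whose members are named, the wording that a list reversed where the sign of its median changed, the comparison within slide 2, the comparison with vehicle 2 as the only vehicle array, and the test of Gene Ontology terms.

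The gene test was tested on simulated data of 22484 genes, drawn independently with 1 SD per gene for both groups. It called 29 of 100 genes changed by a log2 of 1, 93 of 100 changed by a log2 of 2, and 8 unchanged genes, and 0 genes when none was changed. Real genes are correlated, and median deviations from the group mean were 0.16 to 0.21 on vehicle and 0.097 to 0.11 on MOTS-c arrays. These rates therefore need not hold for the real arrays. The list test was simulated at an unadjusted p under 0.05, without the adjustment over lists that was used on the data. With its preset correlation it called 50 of 50 lists of 25 independent members shifted by 0.5 and 2 of 50 unshifted ones. Of unshifted lists whose members shared a correlation of 0.8, it called 28 of 50 with the preset correlation and 0 of 50 with an estimated one. The estimated correlation was not tried on shifted lists, so how many of those it would miss is not known.

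Most alternatives changed 1 choice at a time, while normexp with an offset of 50 was followed by quantile normalization and so changed background and scaling together. The others were quantile normalization alone, median centring, no filter or a stricter filter on dim probes, the mean of a gene's probes or every probe on its own, the replicate number as a block, array weights, eBayes with trend and robust, the slide as a fixed or random block, the authors' deposited normalized values, each array left out in turn, a looser threshold of 0.1, and the other list tests. Normexp ran on median spot signals in place of mean signals, which were not among the columns used here. Leaving out saturated probes was not run, since 0 spots were saturated.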

Results

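Spleen RNA was profiled from female NOD mice, a strain that develops autoimmune diabetes spontaneously. Mice were 6 weeks old at the start and received a daily intraperitoneal injection of either MOTS-c, a short peptide encoded in mitochondrial DNA, at 0.5 mg/kg/day, or a scrambled peptide as vehicle. Spleens were taken at 18 weeks of age after 16 to 18 h of fasting. Each group had 3 arrays, named here vehicle 1 to 3 and MOTS-c 1 to 3, each hybridised with 1 Cy3-labelled sample. Each array held 56605 probes other than controls, 61.8% to 64.0% of its spots were well above background, 0 spots were saturated, and the 75th percentile of its signal lay between 678 and 926. Arrays give no count of molecules, so the precision of each value is set by the 3 arrays of a group. The study's title concerns MOTS-c and loss of islets in autoimmune diabetes, and the only comparison of these arrays is MOTS-c against vehicle: how the spleen's transcripts differ after treatment.

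With MOTS-c, transcripts of red cell precursors and of dividing cells were lower in the spleen: all 23 tested genes of the erythroid list and all 28 of the cell cycle list had lower means, with median log2 differences of -1.19 and -1.13. Nuclear genes of oxidative phosphorylation were lower by a smaller amount, in 39 of 39 genes, with a median of -0.40. Markers of T cells, cytotoxic and NK cells and B cells were higher, in 22 of 22, 19 of 19 and 16 of 16 genes, with medians of 0.93, 0.93 and 0.72. These lymphocyte medians were 0.41, 0.42 and 0.30 without vehicle 1, the array with the lowest values of all 3 lists. Vehicle 1 also had the highest erythroid and cell cycle means, and without it those medians were -0.997 and -0.92. The erythroid and cell cycle means of each MOTS-c array lay below those of each vehicle array. The T cell, cytotoxic and NK cell and B cell means of each MOTS-c array lay above them.

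Across 22484 tested genes, of which 16909 had a symbol and 5575 were probes without one, 2 passed limma's test at an adjusted p under 0.05, both higher with MOTS-c, and 0 passed as lower. More genes had small unadjusted p-values than chance gives on average: 1868 lay under 0.01, where that average is 225. Under 0.05 lay 5583, where it is 1124. Genes are correlated, so the count of a single grouping of the arrays can lie far from such an average. Of the 1868, 449 were higher and 1419 lower with MOTS-c. At an adjusted p under 0.1, 1255 genes passed, 241 higher and 1014 lower, of which 115 and 727 had a symbol. The values of the 3 MOTS-c arrays lay all above those of the 3 vehicle arrays for 3552 genes and all below for 4306. Together these were 34.9% of genes, where chance gives 10% on average, with the same limit. The lower genes were mostly bright ones: among the 10029 genes with a mean above the array's 75th percentile, 861 were lower and 89 higher at an unadjusted p under 0.01, against 147 lower and 173 higher among the 3322 dimmest. The count of 2 depended on single arrays: it was 683 without vehicle 2, 3 without MOTS-c 1, 1 without MOTS-c 2, and 0 without vehicle 1, vehicle 3 or MOTS-c 3, where 4171, 6583 and 3209 genes had an unadjusted p under 0.05. The count under 0.01 was 984, 1076 and 741 without MOTS-c 1, 2 and 3, and 417 with the slide as a block, where 1 gene, lower with MOTS-c, passed.

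Of 36 gene lists fixed before the data were examined, 35 had enough tested members, and 16 passed limma's camera test with its preset correlation, 6 lower and 10 higher. With a correlation estimated for each list 0 passed, with a smallest adjusted p = 0.498 with an estimated correlation and 0 at an unadjusted p under 0.05. That form was simulated on unshifted lists only, so failing it does not show that a list is unchanged. By fry 0 passed, with a smallest adjusted p of 0.110 and 11 lists at an unadjusted p under 0.05, and by camera on ranks 18 passed. The estimated correlation between members of a list reached 0.900, and the 9 other ways of splitting the 6 arrays into 3 and 3 gave 10 to 18 lists by the preset test.

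**Figure D1:**
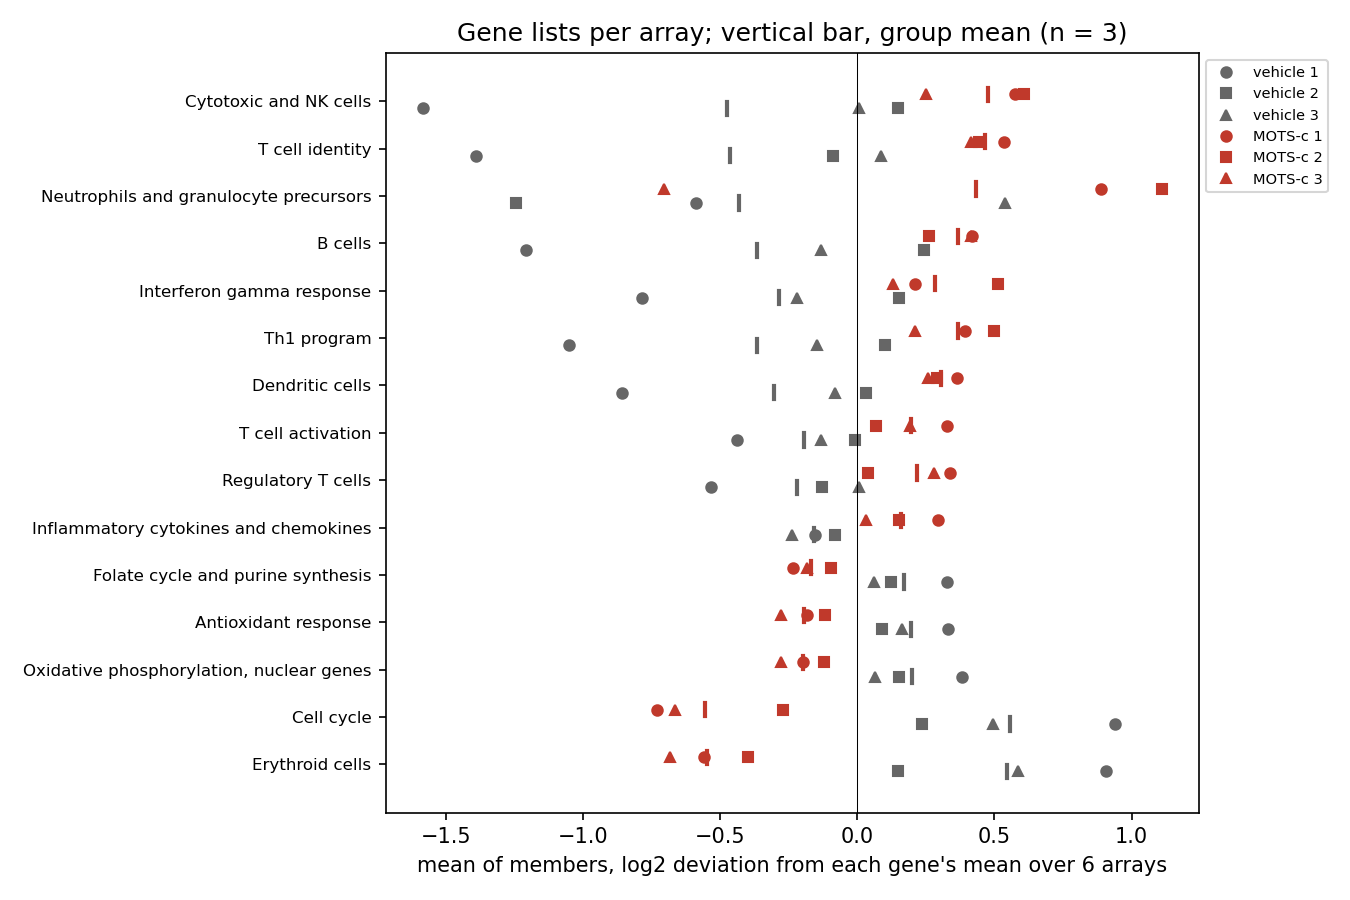
Mean of each list's tested members per array, as the log2 deviation from each gene's mean over the 6 arrays (x axis), for 15 of the 16 lists past the preset camera test; the list of pancreatic acinar genes, whose values span a wider range, is left out. Points are arrays (grey, vehicle; red, MOTS-c; circle, square and triangle for replicates 1, 2 and 3), and vertical bars are group means of 3 arrays. In the erythroid and cell cycle lists each MOTS-c array lies below each vehicle array, and vehicle 1 has the lowest value of the T cell list, at -1.39.

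The erythroid list, markers of red cells and their precursors, fell in MOTS-c spleens (median log2 -1.19, 23 of 23 members lower, camera adjusted p 7.67e-14). The call was lost at adjusted p = 0.498 with an estimated correlation. In 22 of the 23 members the 3 MOTS-c values lay all below the 3 vehicle values. None passed over all genes, and 21 passed at an adjusted p under 0.05 adjusted over the list alone. The mean of the members, as a deviation from each gene's mean, was 0.55 ± 0.38 in vehicle and -0.55 ± 0.14 in MOTS-c (SD, n = 3). Epor, the erythropoietin receptor, was 2.61-fold lower (log2 -1.38 ± 0.25, SE), and Slc4a1, the red cell anion exchanger known as band 3, was 2.49-fold lower (-1.31 ± 0.24). Tspo2, an erythroid relative of the mitochondrial translocator protein, was 2.60-fold lower (-1.38 ± 0.21). Each of these had an adjusted p of 0.0860 over all genes and 0.00305 adjusted over the list alone. The probe for Slc4a1 lies on chromosome 11, positions 102210256 to 102210315, in build mm9.

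The cell cycle list fell by a like amount (median log2 -1.13, 28 of 28 members lower, camera adjusted p 3.99e-17; adjusted p = 0.498 with an estimated correlation). All 28 had MOTS-c values below every vehicle value, with differences from -1.37 to -0.81. Over all genes 0 of them passed, and 28 passed adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, was 2.58-fold lower (log2 -1.37 ± 0.25, SE), and Cdc20, an activator of the anaphase-promoting complex, was 2.26-fold lower (-1.18 ± 0.22). Birc5, which encodes survivin of the chromosomal passenger complex, differed by -1.16 ± 0.21, and Mki67, the gene of the Ki-67 proliferation antigen, by -1.12 ± 0.21. Per array, the mean of the members was 0.94, 0.23 and 0.49 in vehicle 1 to 3, against -0.73, -0.27 and -0.66 in MOTS-c 1 to 3. The probe for Mki67 lies on chromosome 7, positions 142881591 to 142881650, and that for Birc5 on chromosome 11, positions 117716959 to 117717018, in mm9. Both lists kept their calls on each array left out in turn, with medians of -1.47 to -0.997 for the erythroid list and -1.27 to -0.92 for the cell cycle list. Blocking on the slide gave medians of -1.19 and -1.04, the same values as within slide 2, where vehicle 3 is the only vehicle array. With vehicle 2 as the only vehicle array, a comparison chosen after the data were seen, the medians were -0.72 and -0.78.

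Lists of metabolic genes fell as well. Nuclear genes of oxidative phosphorylation had a median log2 difference of -0.40, with 39 of 39 members lower and 33 of them below every vehicle value (camera adjusted p 5.49e-10; adjusted p = 0.498 with an estimated correlation). None passed, over all genes or adjusted over the list alone. Uqcrfs1, the iron-sulphur protein of respiratory complex III, differed by -0.77 ± 0.19 (SE), Ndufv1, a catalytic subunit of complex I, by -0.73 ± 0.18, Cox7a2, a subunit of cytochrome c oxidase, by -0.61 ± 0.16, and Cyc1, cytochrome c1, by -0.55 ± 0.14, with adjusted p-values of 0.0972 to 0.105 over all genes. The median shrank to -0.17 with quantile normalization, -0.20 with normexp followed by quantile normalization and -0.25 with the slide as a block, each still past the preset test. The 11 tested mitochondrially encoded genes had a median of -0.080 that turned to 0.10 with quantile normalization and 0.13 with normexp followed by quantile normalization, with 8 lower and 3 higher, and did not pass (adjusted p 0.574). Of these, ND2 differed by 0.17 ± 0.13 and ATP8 by -0.21 ± 0.17, which turned to 0.037 with quantile normalization and 0.010 with the slide as a block. A test of the difference between the nuclear and the mitochondrial genes was not run.

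The antioxidant list fell (median log2 -0.31, 17 of 21 members lower, camera adjusted p 0.00133; adjusted p = 0.498 with an estimated correlation), and 4 members passed adjusted over the list alone, 0 over all genes. These were Nqo1, a quinone reductase (-1.31 ± 0.24, SE), Gclm, a subunit of the enzyme that starts glutathione synthesis (-1.13 ± 0.22), and the glutathione peroxidases Gpx1 (-0.87 ± 0.20) and Gpx4 (-0.76 ± 0.19). The list of the folate cycle and purine synthesis fell (median -0.29, 18 of 23 lower, camera adjusted p 0.00797; adjusted p = 0.498 with an estimated correlation), with 3 members past the threshold adjusted over the list alone and 0 over all genes. Among those were Shmt2, the mitochondrial serine hydroxymethyltransferase (-0.94 ± 0.16), and Tyms, thymidylate synthase (-1.24 ± 0.28), which is also a member of the cell cycle list. Pfas, an enzyme of purine synthesis, differed by -0.82 ± 0.26. The folate call was lost with the slide as a block, at a median of -0.092 (adjusted p 0.132), and the median was -0.18 without vehicle 1. The antioxidant median was -0.48 without vehicle 3.

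**Figure D2:**
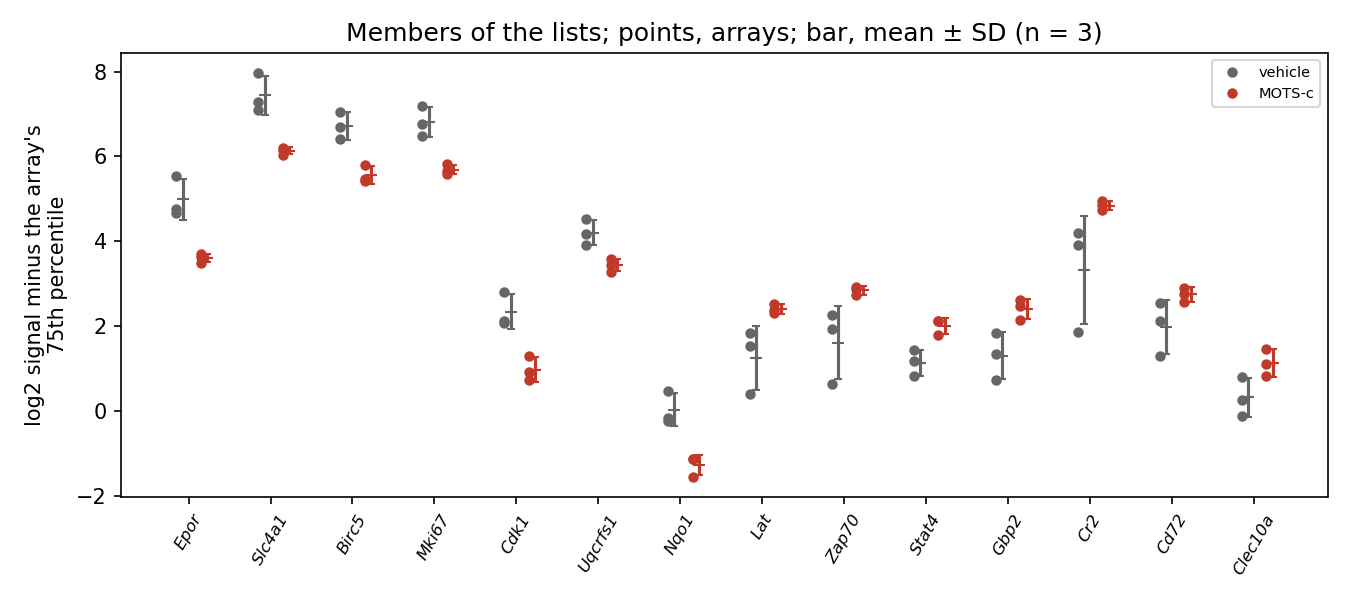
Log2 signal minus the array's 75th percentile (y axis) for 14 members of the lists (x axis), with a point per array (grey, vehicle; red, MOTS-c) and the mean ± SD of 3 arrays beside the points. The spread of vehicle is wider than that of MOTS-c in most of the lymphocyte genes, as in Cr2, at 3.32 ± 1.28 in vehicle and 4.84 ± 0.10 in MOTS-c.

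The T cell identity list rose with MOTS-c (median log2 0.93, 22 of 22 members higher, 20 of them above every vehicle value, camera adjusted p 1.12e-06; adjusted p = 0.512 with an estimated correlation). None passed, over all genes or adjusted over the list alone. Zap70, a kinase of T cell receptor signalling, was 2.35-fold higher (log2 1.23 ± 0.40, SE, adjusted p 0.141). The adaptor Lat differed by 1.14 ± 0.36 and Il7r, a receptor for a T cell survival cytokine, by 1.12 ± 0.35. The cytotoxic and NK cell list rose too (median 0.93, 19 of 19 higher, 8 of them above every vehicle value, camera adjusted p 5.04e-05; adjusted p = 0.540 with an estimated correlation). Klrk1 and Klrd1, receptors of NK cells, differed by 0.80 ± 0.30 and 0.85 ± 0.35, Il2rb by 0.75 ± 0.31 and Gzmb, granzyme B, by 1.29 ± 0.51, and none of the 19 passed over all genes or adjusted over the list alone. The Th1 list rose (median 0.67, 14 of 14 higher, camera adjusted p 5.04e-05; adjusted p = 0.498 with an estimated correlation), with 2 members past the threshold adjusted over the list alone and 0 over all genes: Stat4, the transducer of interleukin signals that drive Th1 cells (0.87 ± 0.20), and Havcr2, which encodes the inhibitory receptor TIM3 (0.63 ± 0.15). Runx3 and Hlx, transcription factors of Th1 cells, differed by 0.73 ± 0.24 and 0.60 ± 0.18. Vehicle 1 set much of the size of all 3 lists, whose medians without it were 0.41, 0.42 and 0.40. They were 0.38, 0.51 and 0.52 with the slide as a block, and each call was kept. With vehicle 2 as the only vehicle array, a comparison chosen after the data were seen, they were 0.45, 0.26 and 0.29.

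B cell markers rose (median log2 0.72, 16 of 16 higher, 8 of them above every vehicle value, camera adjusted p 2.47e-04; adjusted p = 0.540 with an estimated correlation). Cr2, the complement receptor of B cells and follicular dendritic cells, was 2.87-fold higher (1.52 ± 0.57, SE), Spib, a B cell transcription factor, 2.11-fold (1.08 ± 0.45), and Cxcr5 and Cd72 differed by 0.87 ± 0.32 and 0.77 ± 0.32. The dendritic cell list rose (median 0.62, 13 of 14 higher, camera adjusted p 0.00492; adjusted p = 0.498 with an estimated correlation), with Ccr9 at 1.11 ± 0.47, Clec4a4 at 0.91 ± 0.39, Clec10a at 0.81 ± 0.28 and Flt3 at 0.63 ± 0.22, though another probe of Flt3 read -0.23. Genes induced by interferon gamma rose (median 0.68, 20 of 23 higher, camera adjusted p 2.47e-04; adjusted p = 0.540 with an estimated correlation). Among them, Iigp1, an immunity-related GTPase, differed by 1.24 ± 0.43, Gbp2, a guanylate-binding protein, by 1.1 ± 0.29, Nlrc5, an activator of MHC class I genes, by 1.02 ± 0.30, and Irgm1 by 0.60 ± 0.17, though other probes of Irgm1 ran from -0.55 to 0.83. No member of these 3 lists passed, over all genes or adjusted over the list alone. Without vehicle 1 the medians of the B cell, dendritic cell and interferon gamma lists were 0.30, 0.36 and 0.35, and with the slide as a block that of the dendritic cell list was 0.37, each still past the preset test. With vehicle 2 as the only vehicle array, a comparison chosen after the data were seen, they were 0.14, 0.11 and 0.069, and none passed (adjusted p 0.248, 0.117 and 0.248).

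The list of regulatory T cell genes rose (median log2 0.41, 16 of 17 higher, 3 of them above every vehicle value, camera adjusted p 0.00359; adjusted p = 0.498 with an estimated correlation). Its call was lost with the slide as a block, at a median of 0.17 (adjusted p 0.107), and its median was 0.26 without vehicle 1. It was also lost with vehicle 2 as the only vehicle array, at 0.28 (0.0515), a comparison chosen after the data were seen. Tnfrsf18, the receptor GITR, differed by 1.25 ± 0.45 (SE), Gpr83 by 1.04 ± 0.36, Itgae by 0.77 ± 0.29 and Entpd1, the ectoenzyme CD39, by 0.53 ± 0.18. Foxp3, the transcription factor that defines the lineage, differed by 0.14 ± 0.29 (adjusted p 0.780). T cell activation genes rose (median 0.46, 13 of 14 higher, camera adjusted p 0.0163; adjusted p = 0.498 with an estimated correlation), but without MOTS-c 1 the call was lost (median 0.32, adjusted p 0.0575), and without vehicle 1 the median was 0.29. With vehicle 2 alone the median was 0.16 (0.265) and the call was lost. Icos, Egr2, Nfatc1 and Batf differed by 0.69 ± 0.25, 0.70 ± 0.34, 0.60 ± 0.25 and 0.43 ± 0.21. Inflammatory cytokines and chemokines rose (median 0.31, 14 of 17 higher, camera adjusted p 0.0472; adjusted p = 0.498 with an estimated correlation). That call was lost without vehicle 2, vehicle 3 or MOTS-c 1, at an adjusted p of 0.0708, 0.117 and 0.131, and with quantile normalization alone, after normexp or with the mean of a gene's probes, at 0.0712, 0.0867 and 0.0645. It was lost with vehicle 2 alone too (median 0.19, adjusted p 0.125). With the slide as a block the median was 0.50 (adjusted p 0.0280). Ccl3, a chemokine, differed by 0.76 ± 0.21, Ccl2 by 0.72 ± 0.30, Tnf by 0.65 ± 0.25 and Csf1 by 0.55 ± 0.25. No member of these 3 lists passed, over all genes or adjusted over the list alone. The regulatory T cell and activation medians, like that of the Th1 list at 0.67, were smaller than the 0.93 of T cell identity. Without vehicle 1 these medians, in that order, were 0.26, 0.29, 0.40 and 0.41. With the slide as a block they were 0.17, 0.32, 0.52 and 0.38. Whether any of these lists rose beyond the T cell markers was not tested.

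Neutrophil and granulocyte precursor genes rose by the preset test (median log2 0.89, 19 of 20 higher, camera adjusted p 0.00797; adjusted p = 0.625 with an estimated correlation), yet in 0 of the 20 members did the groups separate. None passed over all genes or adjusted over the list alone. Per array the mean of the members was -0.59, -1.24 and 0.54 in vehicle 1 to 3 and 0.89, 1.11 and -0.70 in MOTS-c 1 to 3. The median turned to -0.069 with the slide as a block (adjusted p 0.914). The call was lost without vehicle 2 (median 0.46, adjusted p 0.152) and without MOTS-c 2 (0.56, adjusted p 0.0939), and the median was 1.36 without vehicle 3 and 1.5 without MOTS-c 3. Mmp8, a neutrophil collagenase, differed by 1.30 ± 0.43 (SE), Cxcr2, a chemokine receptor of neutrophils, by 0.88 ± 0.38, Retnlg by 1.05 ± 0.47 and Ltf, lactoferrin, by 1.58 ± 0.93. With 1 array left out these ran from 1.06 to 1.68, 0.52 to 1.13, 0.71 to 1.57 and 0.85 to 2.45.

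Transcripts of digestive enzymes and other secretory products of pancreatic acinar cells, from the organ that lies beside the spleen, were read at very different levels on the 6 arrays. The list fell by the preset test (median log2 -3.03, 23 of 23 lower, camera adjusted p 5.04e-05; adjusted p = 0.540 with an estimated correlation), but only 3 members separated the groups, and 23 of 23 were highest in vehicle 3. The mean of the members was 1.22, -1.43 and 4.31 in vehicle 1 to 3 and -1.69, -2.44 and 0.039 in MOTS-c 1 to 3. Without vehicle 3 the median was -1.44, with the slide as a block -6.49, and with vehicle 2 as the only vehicle array, a comparison chosen after the data were seen, it was 0.20. Reg1, Zg16 and Pla2g1b differed by -4.03 ± 1.84 (SE), -2.08 ± 0.88 and -0.96 ± 0.24, and none of the 23 passed over all genes or adjusted over the list alone. With 1 array left out these differences ran from -5.76 to -2.07, -2.81 to -0.95 and -1.21 to -0.82. Of 10 listed pancreatic endocrine genes, too few were well above background for a test; the tested ones were Gcg, at -3.93, -4.14 and -3.54 in vehicle 1 to 3 and -4.11, -4.12 and -3.98 in MOTS-c 1 to 3, and Pcsk2.

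The other 19 lists did not pass. T cell exhaustion and fatty acid oxidation lay closest, with medians of 0.40 (adjusted p 0.0501) and -0.13 (0.0503). Each passed in 2 of the 6 fits with 1 array left out, over which the medians ran from 0.28 to 0.60 and from -0.24 to -0.051. Acsl1, an acyl-CoA synthetase, differed by -1.19 ± 0.25 (SE) and Etfa by -0.49 ± 0.15. The Th17 list had a median of 0.30 (adjusted p 0.0935), or 0.18 without vehicle 1, and the Th2 list 0.46 (0.0946), in which Stat6 differed by 0.46 ± 0.14. The Th2 median turned to -0.062 with no filter on dim probes. Genes of the type I interferon response had a median of 0.42 (0.0946), ran from 0.093 without vehicle 1 (0.436) to 0.79 with 1 array left out, passing in 2 of 6, and went both ways: 3 members were higher and 3 lower past the threshold adjusted over the list alone, among them Oasl2 at 1.27 ± 0.28 and Isg20 at -1.12 ± 0.21. Glycolysis had a median of 0.24 (0.104; 0.14 to 0.28 with 1 array left out), although its members with the smallest p-values were lower, the lactate transporter Slc16a1 by -1.06 ± 0.22 and the phosphofructokinase Pfkm by -1.03 ± 0.22. AMPK and mTOR signalling genes had a median of -0.094 (0.174), 0.014 with quantile normalization and -0.0089 without vehicle 1, with the autophagy kinase Ulk1 at -1.02 ± 0.27 and the translation repressor Eif4ebp1 at -0.92 ± 0.20. Macrophage and monocyte genes had a median of 0.074 (0.502), with Ly6c1 and Ly6c2 at 0.78 ± 0.30 and 0.73 ± 0.28.

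Medians of the integrated stress and unfolded protein response and of immediate early and heat shock genes were 0.020 (adjusted p 0.712) and -0.046 (0.887), the latter 0.029 with quantile normalization. In the stress list the mean of -0.11 and camera's direction were lower while the median was higher, with Chac1 at -1.73 ± 0.44 (SE) and Asns, asparagine synthetase, at -1.24 ± 0.30. In the immediate early list camera's direction was higher while median and mean were lower. The remaining medians were 0.26 for mesothelium, 0.27 for plasma cells, 0.21 for stromal and endothelial cells and 0.24 for megakaryocytes and platelets (each at adjusted p 0.10), 0.36 for germinal centre genes (0.104), -0.087 for adipocytes (0.502), 0.094 for mast cells and basophils (0.712) and -0.053 for fatty acid and cholesterol synthesis (0.712); with normexp followed by quantile normalization those of adipocytes and mast cells turned to 0.013 and -0.000603. With 1 array left out the medians ran from 0.077 to 0.39 for mesothelium (2 of 6 fits passed), 0.080 to 0.55 for plasma cells (2), 0.10 to 0.31 for stromal and endothelial cells (1), 0.022 to 0.56 for megakaryocytes and platelets (3), 0.12 to 0.47 for germinal centre genes (1), -0.50 to 0.39 for adipocytes (1) and -0.16 to -0.014 for fatty acid and cholesterol synthesis (0). The lowest of plasma cells, stromal and endothelial cells, megakaryocytes and germinal centre genes were those without vehicle 1. With the slide as a block, lists that had not passed the preset camera test did so. They were megakaryocytes and platelets at -0.42 (adjusted p 0.0196), mesothelium at 0.30 (0.0196) and immediate early and heat shock genes at 0.31 (0.0320). Fatty acid oxidation at -0.25 (0.0320) and plasma cells at 0.31 (0.0400) passed too. These medians are the same as within slide 2, so they rest on vehicle 3 as the only vehicle array. Vehicle 3 is also the array with the highest acinar values.

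Among single genes chosen for their role in T cell differentiation and in MOTS-c signalling before the data were examined, 0 passed over all genes. Il17a was not well above background on any array, nor were Il2 and Ppargc1a. Ifng differed by a log2 of 1.18 ± 0.77 (SE) and was well above background on 2 of 3 vehicle arrays, and its regulator Tbx21 differed by 0.68 ± 0.35. Il4, well above background on 2 of 3 vehicle arrays, and Gata3, of the Th2 program, differed by 1.04 ± 0.38 and 0.85 ± 0.39. Il2ra differed by 0.55 ± 0.36, Ctla4 by 0.28 ± 0.35 and Il10 by -0.37 ± 0.66, and Il10 and Foxp3 turned to 0.27 and -0.15 without vehicle 1, Il10 to 0.19 without MOTS-c 2 and to 0.17 with the slide as a block, and Ctla4 to -0.027 without vehicle 2. Cd4 and Cd8a differed by 0.58 ± 0.24 and 0.70 ± 0.45. These sizes rested in part on vehicle 1, without which Ifng, Tbx21, Il4, Gata3, Il2ra, Cd4 and Cd8a differed by 0.32, 0.32, 0.62, 0.37, 0.14, 0.33 and 0.16. With vehicle 2 as the only vehicle array, a comparison chosen after the data were seen, Foxp3, Ifng and Cd8a turned to -0.47, -0.29 and -0.060. Il10 turned to 0.38. Blocking on the slide gave 0.39 for Gata3, 0.27 for Il2ra, 0.073 for Ctla4, 0.20 for Cd4 and 0.38 for Cd8a. Prkaa1, a catalytic subunit of AMPK, differed by -0.21 ± 0.17 (-0.11 without vehicle 1 and -0.34 without vehicle 2) and by 0.018 at its other probe, and Mtor by 0.15 ± 0.12, while its dimmer probe read -1.98. Gapdh, a common reference gene, differed by -0.22 ± 0.15 (-0.14 without vehicle 1, -0.088 with the slide as a block). Of 120 genes whose differences were followed through the alternatives, named or not, 35 had differences smaller by over 1.5 times without vehicle 1 and 38 with the slide as a block; this count was made after the data were seen.

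The genes past the threshold were 2 probes without a symbol, named here after their values were seen. Probe A_55_P2725926 was at least 4.49-fold higher with MOTS-c (adjusted p 0.0119) and probe A_55_P2743807 at least 2.42-fold higher (adjusted p 0.0187). Both were well above background on 3 of 3 MOTS-c arrays and on 0 of 3 vehicle arrays. Neither passed without vehicle 1 (adjusted p 0.108 for both), vehicle 3 (0.0704) or MOTS-c 3 (0.0523 and 0.0964), nor the first of them without MOTS-c 2 (0.0794). With each array left out their bounds were 4.05- to 5.08-fold and 2.03- to 2.70-fold. Both calls were lost too with the slide as a block (adjusted p 0.118 and 0.224), the replicate block (0.0589 for both) and no filter on dim probes (0.0881 and 0.120), and the call of the second with array weights (0.0535). Neither passed with normexp followed by quantile normalization (adjusted p 0.0672 for both). Their log2 differences there were 1.08 and 0.70, so the bounds do not hold under that processing. Their mean vehicle levels were -7.67 and -7.77, while the lowest signal well above background on the vehicle arrays was -5.75 to -5.44. The limma p-values of both therefore rest in part on the spread of vehicle values below that signal. Most genes with the largest positive differences that did not pass were dim in the same way: on 0 of 3 vehicle arrays were Rbm44, Alpk2, Dnajb8, Wfdc6b, Defb26, Papln and Wfdc6a well above background, and they were at least 2.70-, 2.24-, 2.13-, 2.42-, 2.31-, 3.05- and 2.45-fold higher (adjusted p 0.0860 to 0.0933). Without MOTS-c 3 these bounds were 2.23, 2.48, 1.58, 1.91, 1.89, 2.19 and 1.99, a comparison made after the data were seen. Kif12, a kinesin, has no bound here: its tested probe was well above background on 0 of 3 vehicle arrays, but an untested probe of the gene was on 1 of them. Alox15, a lipoxygenase, differed by 2.46 ± 0.38 (SE, adjusted p 0.0860) and was well above background on 2 vehicle arrays, as was Gbp2b, an interferon-induced guanylate-binding protein (1.94 ± 0.51, adjusted p 0.105). The tested probes of Eml6 and of the T cell ADP-ribosyltransferase gene Art2b, well above background on 1 vehicle array, differed by 2.10 ± 0.30 and 1.93 ± 0.53; counting its untested probes, Eml6 was well above background on 2 vehicle arrays. Blocking on the slide gave 1.17 for Gbp2b and 0.93 for Art2b.

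Erfe, which encodes erythroferrone, a hormone that red cell precursors release to lower hepcidin, was among the genes with the largest negative differences. Its level was -0.50 ± 1.51 in vehicle and -3.80 ± 0.81 in MOTS-c (SD, n = 3, log2 relative to the 75th percentile), a difference of -3.30 ± 0.76 (SE, adjusted p 0.0897), and its other probe read -3.27. The Erfe probe lies on chromosome 1, positions 93270468 to 93270527, in mm9. Not well above background on any MOTS-c array were Apol8, Oxct2a, Msmb, Arhgdig and Trim15, at least 3.96-, 3.31-, 3.21-, 2.34- and 2.39-fold lower (adjusted p 0.0860 to 0.101). Without vehicle 1 these bounds were 2.17, 1.86, 2.13, 1.66 and 1.98, without vehicle 3 they were 6.66 and 5.66 for Apol8 and Oxct2a, and against vehicle 3 alone, the vehicle array of slide 2, they were 1.41, 1.13, 2.13, 1.25 and 2.64, comparisons made after the data were seen. H2bc22, a replication-dependent histone gene, differed by -2.51 ± 0.42 (adjusted p 0.0860), Nacad by -2.59 ± 0.33 (0.0860), Slc51a, an organic solute transporter subunit, by -2.40 ± 0.62 (0.102) and Bmp8b, a growth factor of the BMP family, by -2.44 ± 0.53 (0.0866). Serinc2, well above background on 1 MOTS-c array, differed by -2.50 ± 0.67 (0.109). Ginm1 differed by -2.72 ± 0.77 (0.120) at 1 probe and by -0.14 at the other. With the slide as a block Erfe, Ginm1, Slc51a and Serinc2 differed by -1.89, -0.82, -1.07 and -4.02.

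**Figure D3:**
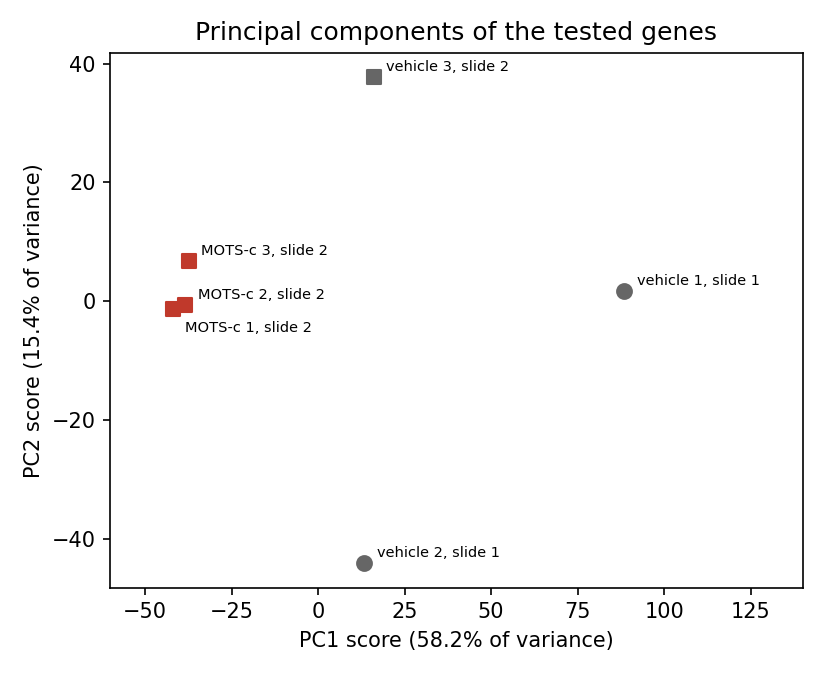
Principal components of the tested genes, with component 1 (x axis, 58.2% of the variance) and component 2 (y axis, 15.4%); each point is an array, grey for vehicle and red for MOTS-c, circles for slide 1 and squares for slide 2. The MOTS-c arrays lie together at -42.1 to -37.4 on component 1, and vehicle 1 lies apart at 88.4.

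The MOTS-c arrays were more alike than the vehicle arrays. Pearson correlations across tested genes, which are not independent replicates, were 0.991 to 0.992 between MOTS-c arrays, 0.978 to 0.984 between vehicle arrays and 0.959 to 0.984 between the groups. The lowest were those of vehicle 1, at 0.959 to 0.980 with the other 5 arrays. Vehicle 1 and 2 were on slide 1, and vehicle 3 was on slide 2 with all 3 MOTS-c arrays. A comparison within a slide therefore rests on vehicle 3 as the only vehicle array.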

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

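The comparisons within slide 2 (vehicle 3 against MOTS-c) and with vehicle 2 as the only vehicle array were chosen only after results were seen; the others were set beforehand. Each rests on 1 vehicle array, assumed to vary like the MOTS-c arrays. The count of 2 genes past the threshold, both higher, was the same with quantile normalization, median centring, the mean of a gene's probes, every probe on its own and the slide as a random block. It was 0, with 0 higher, with normexp, no filter on dim probes, the stricter filter, the replicate block, the authors' deposited values, within slide 2 and with vehicle 2 alone, where limma gave 5900, 6023, 5236, 4627, 5376, 4221 and 4524 genes at an unadjusted p under 0.05. The stricter filter and the authors' deposited values leave out both passing probes, which were not well above background on any vehicle array. Their counts of 0 therefore do not test those probes again. The count was 1 gene, higher, with array weights and 437 with eBayes with trend and robust (47 higher, 390 lower). At an adjusted p under 0.1 it was 1255 (241 higher, 1014 lower). With the slide as a block it was 1 (0 higher, 1 lower), with 417 genes at an unadjusted p under 0.01. Leaving out each array gave 0 to 683 genes (0 to 91 higher, 0 to 592 lower), 741 to 2399 at an unadjusted p under 0.01, and 15 to 21 lists. The count of lists was 25 without a filter, 10 with vehicle 2 alone, 0 with an estimated correlation and 0 by fry. The mean correlation within groups minus that between groups was 0.0104, and 0.0944 for the 1000 most variable probes. The cause was not tested. Pairs by the titles' numbers, which the descriptions of vehicle 3 and MOTS-c 3 do not share, were not closer: deviations of same-numbered samples correlated at -0.172, 0.0337 and -0.0732, and the vehicle arrays correlated best with MOTS-c 3, 1 and 1. With the replicate block 0 genes and 18 lists passed.

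Of the single genes followed, only 2 had passed in the main fit. For the others, keeping the side of the threshold means not passing again, whatever the size of the difference. Among single genes under alternatives set beforehand, 2155 values kept direction and side of the threshold, 49 came to pass, 16 no longer passed and 10 reversed. Among list medians these were 578, 46, 43 and 33. Under the added alternatives they were 229, 0, 4 and 7 for genes and 41, 6, 8 and 15 for lists. With quantile normalization the reversed log2 values were 0.037 for ATP8, 0.10 for mitochondrially encoded genes, 0.029 for immediate early genes and 0.014 for AMPK and mTOR signalling; with the authors' deposited values they were 0.036, 0.10, 0.028 and 0.013. With normexp, then quantile normalization, mast cells were at -0.000603, adipocytes at 0.013, immediate early genes at 0.038 and mitochondrially encoded genes at 0.13. Array weights gave -0.023 for mast cells and 0.11 for immediate early genes. Without a filter the Th2 list was at -0.062. Mtor was at -0.92 with the mean of its probes and -1.98 at its dimmer probe. With the slide as a block, and alike within slide 2, Il10 was at 0.17, ATP8 at 0.010, macrophages at -0.046, neutrophils at -0.069, mast cells at -0.12, megakaryocytes at -0.42, immediate early genes at 0.31, mitochondrially encoded genes at 0.010, fatty acid and cholesterol synthesis at 0.12 and the stress and unfolded protein response at -0.090. With vehicle 2 alone, Foxp3 was at -0.47, Il10 at 0.38, Ifng at -0.29, Cd8a at -0.060, Prkaa1 at 0.058, plasma cells at -0.14, acinar genes at 0.20, adipocytes at 0.11, the type I interferon response at -0.26, immediate early genes at 0.14, AMPK and mTOR signalling at 0.046 and the stress response at -0.10. Leaving out each array, the values that reversed ran from -0.15 to 0.44 for Foxp3, -0.027 to 0.57 for Ctla4, -0.74 to 0.27 for Il10, -0.020 to 0.12 for macrophages, -0.26 to 0.44 for mast cells, -0.50 to 0.39 for adipocytes, -0.19 to 0.20 for immediate early genes and -0.056 to 0.049 for the stress response. The cause of these reversals was not tested. Signal over background limits the dim genes: 3322 of the tested genes had a mean under -4.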

Other observations

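The tests in this part were chosen only after results were seen, while the slide as a block and leaving out an array were among the alternatives set beforehand. Gene Ontology terms of 20 to 200 tested genes were compared by limma's camera with the preset correlation: of 1395 terms over 14640 genes, 94 passed, 64 lower and 30 higher with MOTS-c, and 0 passed with an estimated correlation (smallest adjusted p = 0.855 with an estimated correlation). Genes of the nucleosome were lower, 44 of 51 with a median log2 of -0.93 (adjusted p 2.78e-09), among them H2bc22 and H2ax, and 0 of them belong to the fixed lists. Genes of the centromeric region of chromosomes were lower in 106 of 125 cases with a median of -0.60 (adjusted p 1.22e-12), led by Sgo2a, Cenph and Cenpf. Nuclear pore genes (44 of 50 lower, median -0.42, adjusted p 1.36e-06), proteasome genes (53 of 58, -0.38, 2.48e-06) and ribosome genes (138 of 153, -0.16, 1.74e-04) were lower by less. Higher were genes of the defense response to protozoans, 20 of 21 with a median of 0.43 (adjusted p 0.00221), 10 of them members of the fixed lists. This term includes the guanylate-binding proteins Gbp2, Gbp6, Gbp9 and Gbp10. Genes of peptide antigen binding, 24 of 28 with a median of 0.47 (0.00234), include the MHC class I genes H2-M11, H2-Q2 and H2-Q10, and B cell receptor signalling genes were higher in 23 of 25 cases, with a median of 0.54 (7.45e-04).

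The erythroid and cell cycle lists were lower and the T cell list higher with MOTS-c. Vehicle 1 was not the only vehicle array to differ: without it the list means still differed by -0.92 ± 0.19, -0.92 ± 0.21 and 0.46 ± 0.080 (SE), which is -4.708, -4.399 and 5.842 standard errors. These lists were picked for this test after their values were seen. Their array means already separated the groups, so the direction of what remained was fixed. The standard errors rest on vehicle 2 and 3 alone, and the T cell median fell from 0.93 to 0.41. The slide stays open for the erythroid list: with it as a block the median stayed at -1.19 (adjusted p 1.99e-15) while that of neutrophils moved from 0.89 to -0.069, but this rests on the 1 vehicle array of slide 2, from which the MOTS-c arrays differed by -1.134 with an SD of 0.14 among them. A smaller share of erythroid cells, which would raise all other cell types alike, stays open as a candidate explanation: the T cell list exceeded the macrophage list by 0.82 ± 0.43, or 1.912 standard errors. That value keeps vehicle 1, whose T cell mean was -1.39, against -0.088 and 0.086 in vehicle 2 and 3. Without vehicle 1 the T cell and macrophage medians were 0.41 and 0.015, and their difference was not tested. An effect of the treatment on erythropoiesis or on proliferation stays open too, and no test here separates it from these.

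Pancreatic acinar transcripts were highest in vehicle 3 for 100% of 23 tested members, with a median log2 gap of 3.07 to the next array and a largest gap of 4.54. Pancreatic tissue in the vehicle 3 sample stays open, since that share restates the pattern and decides nothing. An effect of treatment stays open too: without vehicle 3 the list mean differed by -1.26 ± 1.37, or -0.919 standard errors.

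Probes well above background on all 3 arrays of 1 group and on none of the other, with a log2 gap over 1, numbered 133, of which 73 were read in MOTS-c only and 60 in vehicle only. Their median distance to the nearest other was 12.2 spots, against 10.2 in random sets of dim probes, at percentile 99.6 of 1000 sets, which decides nothing on a local flaw of an array, as the probes were selected over all 6. The slide, an effect of the treatment and other differences between the samples stay open: that these probes read alike in the vehicle arrays of both slides is fixed by their selection.

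The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold the real split gave 2 and the highest other 0, so that 1.0 split, the real one, gave as many, and so it was for genes higher, at 2 against 0. The gene and list counts of every split used the genes kept by the filter on the real groups. Both passing probes were kept only through the MOTS-c arrays, so the other splits had no like chance. The stricter filter leaves out both of these probes, and with it the real split gave 0 as well. For genes lower it gave 0 and all 10 splits did. For genes at an unadjusted p under 0.01 it gave 1868 against 164 (1.0 split as large), and for the probes read in 1 group only 133 against 46 (1.0 split). For lists past the preset test it gave 16 against 18, and 4.0 splits gave as many; vehicle 1 and 2 of slide 1 were together in 1 of those others, with MOTS-c 3.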
